A study of Homo sapiens with 8 samples.

How the data were processed

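The series holds 8 libraries of HUES6, an established line of human embryonic stem cells: 4 eCLIP libraries and 4 input libraries. Per the labels' protocols, dishes of about 20M cells were irradiated with UV light at 400 mJ/cm2, RNA bound to protein was pulled down with an antibody against RBPMS, and libraries were made by the published eCLIP procedure and sequenced as paired ends of 75 nt. Each eCLIP library has 1 peak list, and the input libraries have no list of their own, so the comparison of each immunoprecipitation with input is the one already held in the deposited values.

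Each list gives, per peak, chromosome, start, end, strand and 2 values that the authors made. The first is the deposited −log10 p of immunoprecipitation against input, from 0 to 400. The second is the deposited log2 fold of immunoprecipitation over input. Peaks were called per library and not on pooled libraries, as shown by 1 list per library with its own coordinates. The coordinates are on build hg19, per the submitters' processing notes, and on 15 of 23 chromosomes they reach past the last gene of the GRCh38 annotation at hand, which was therefore not used. The aligner, the peak caller and which input library entered each list are not given in the sources used here. A peak's log2 fold and p are the authors' values, and they were used to describe, rank and filter peaks; the correlation of log2 folds between lists and their means over libraries describe agreement only.

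The read numbers behind each peak were worked out from the deposited pairs of values. The log2 fold equals the log2 ratio of 2 whole read numbers plus a constant per library, and the p matches Fisher's exact test, or the chi-square test with continuity correction where both read numbers are at least 5, within a relative tolerance of 0.003. This gave unique read numbers for 92.5% to 98.3% of the peaks with log2 above 0 and −log10 p below the ceiling of 15.7. On simulated reads at the same depth ratios, 99.6% of 7638 peaks came back, with 0 wrong. The simulated p came from the same tests and constants, so this checks the working back only. It cannot show that the authors' p were made in this way. The constant gives the depth of input over immunoprecipitation, 3.18, 1.04, 2.12 and 1.46 in libraries 1 to 4. Total reads per library could not be worked out. Among the peaks with recovered reads none rested on fewer than 3 immunoprecipitation reads. The working back allowed no input below 1 read, so an input of 0 and of 1 cannot be told apart. A log2 fold with 1 input read therefore depends on how the authors treated 0. All peaks with log2 below 0 carry a −log10 p of 0, so loss against input was not tested. Many p values stop at that ceiling or at 400, and those have no order.

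An enriched peak was one with log2 of at least 3, 8-fold over input, and −log10 p of at least 3. Enriched peaks of the 4 libraries that shared at least 1 base on the same strand were merged into regions, and a region with enriched peaks of at least 3 of 4 libraries was called reproducible. Overlaps were found with bedtools 2.31.1, and all other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The number of reproducible regions was set against 100 seeded permutations of the enriched status among the listed peaks within each library. Added after seeing the data was a second permutation, which moved the status only among peaks listed in the same number of libraries, and both were repeated with libraries 3 and 4 joined as 1 sample. The region count recovered all 300 planted regions in simulated data. These lay far apart, so this checks the counting only and not regions that lie side by side. Agreement was measured as Pearson and Spearman correlation of log2 fold across overlapping peaks of each of the 6 pairs. A region's log2 fold in a library was the highest of its enriched peaks there, so a wide region with several peaks can gain. Its −log10 p was the highest likewise, taken separately, and may belong to another peak. The regions named in the text are the 10 with the highest mean log2 over libraries among those enriched in all 4 libraries. The thresholds, the tests of enriched peaks, reproducible regions and agreement, and the rule for named regions were fixed before the data were examined.

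The libraries were compared before they were averaged, by a chi-square test of the immunoprecipitation reads over peaks paired one to one, with at least 80% overlap of the longer peak and at least 40 reads in both together. Libraries 3 and 4 differed by less than the sampling noise and were therefore, after seeing the data, counted as 1 sample. A mean ± SD is thus over n = 3 samples, libraries 1, 2 and the mean of 3 and 4. The exceptions name pairs, regions, permutations or draws instead. An exact two-sided sign-flip permutation test over 3 samples cannot go below p = 0.25. Nothing states that the libraries come from separate cultures, so their spread may be technical. Binomial intervals cover counting error only.

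The comparisons of runs, chromosomes, chromosome ends and mitochondrial peaks were added after seeing the data. Regions with gaps of at most 1 kb on the same strand were joined into runs. The share of peaks within 5 Mb of a chromosome end and the share on each chromosome were compared between enriched and other peaks per peak, and again with peaks at most 5 kb apart counted once. The chromosome end was the last listed position, and the short arms of chromosomes 13, 14, 15, 21 and 22 were left out. Alternatives were a stricter p, a looser fold, other numbers of libraries, a larger overlap and each library left out. The share of peaks in 3′ untranslated regions, the search for paired CAC motifs and the gene lists were planned but not run, since an hg19 genome and annotation were not used here; regions are therefore given by position alone, with no gene, exon or UTR.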

Results

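The data describe which RNA was enriched over input by an antibody against RBPMS, an RNA-binding protein, after crosslinking in HUES6 human embryonic stem cells. Crosslinked RNA was immunoprecipitated with an RBPMS antibody in 4 eCLIP libraries, and each was set against input RNA, which was not immunoprecipitated. The 4 input libraries enter only through the authors' log2 fold and p per peak. Libraries 1, 2, 3 and 4 listed 25759, 118375, 20254 and 29615 peaks. Among the peaks whose read numbers could be worked out, the median was 3 immunoprecipitation reads in libraries 1 and 3 and 4 reads in libraries 2 and 4.

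Libraries 3 and 4 differed by less than the sampling noise and were counted as 1 sample. Over 246 shared peaks their immunoprecipitation reads gave a chi-square of 0.88 per degree of freedom (chi-square test, p = 0.905), and each of the other 5 pairs gave 3.59 to 4.62. Library 4 held 1.66 times the immunoprecipitation reads of library 3 over the peaks both listed whose read numbers could be worked out. Means below are over n = 3 samples, except where pairs, libraries, regions, permutations or draws are named.

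The first comparison asked which peaks stood above input in each library. Peaks at least 8-fold over input, with −log10 p of at least 3, numbered 4107 in library 1, 6370 in library 2, 2548 in library 3 and 3749 in library 4, with a median of 3928 over libraries and a mean of 4542 ± 1654 (SD, n = 3). They made up 15.9% (Wilson 95% interval 15.5 to 16.4), 5.38% (5.25 to 5.51), 12.6% (12.1 to 13.0) and 12.7% (12.3 to 13.0) of the listed peaks. Their median log2 fold lay between 4.15 and 4.54, and 52.8% ± 0.84 (SD, n = 3) of them were on the plus strand. Their median width was 75 to 89 bases. The thresholds could be met with 7 immunoprecipitation reads over 1 input read in library 1 but needed 13 in library 2, 8 in library 3 and 10 in library 4, so the counts are not set against each other as a difference in binding.

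The second comparison asked which enriched regions recurred. Merging gave 7472 regions, of which 4537 were enriched in 1 library, 1236 in 2, 759 in 3 and 940 in 4. The 1699 regions enriched in at least 3 of 4 libraries were the reproducible set, with 910 on the plus strand, 789 on the minus strand and a median width of 168 bases. Of these, 1260 were enriched in all 3 samples and 439 in 2 samples. With enriched status shuffled within each library, 42.4 ± 6.51 regions (SD of 100 permutations) reached 3 libraries, at most 60, and 2.16 reached all 4 (permutation p = 0.0099, the smallest that 100 draws can give). Shuffling only among peaks listed in the same number of libraries gave 1632 regions (SD 21.3, at most 1686; permutation p = 0.0099, the smallest possible) against the observed 1699. The same shuffle gave 497 regions in all 4 libraries (SD 15.8, at most 533) against the observed 940. Both shuffles moved libraries 3 and 4 independently. With these joined as 1 sample and the status shuffled within each sample, 8.46 regions were enriched in all 3 samples (at most 16), and shuffling only among peaks listed in the same number of samples gave 672 (SD 21.8, at most 716), against the observed 1260 (permutation p = 0.0099 for both, the smallest possible). For at least 2 of 3 samples the latter shuffle gave 2791 regions (SD 27.4) against 2789 in the data, counted after overlapping peaks of libraries 3 and 4 were joined (permutation p = 0.505), a difference within the spread of the shuffles. The count changed over 1.5-fold with the number of libraries asked for, to 2935 for at least 2 and 940 for all 4. Without library 3, and with at least 2 of the other 3 libraries asked for, it was 2685.

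The region with the highest mean log2 fold over libraries lay on chromosome 16, positions 4394383 to 4394657, minus strand, at 8.23 ± 2.06 (SD, n = 3), from 5.98 in library 1 to 10.04 in library 2. Without library 2 it stood at 7.32, below the next region. A region on chromosome 6, 157731567 to 157731799, minus strand, reached 8.17 ± 0.36, with 7.78 as its lowest library value and 8.14 as its mean without library 2. On chromosome 13, 113539437 to 113539664, plus strand, the log2 fold was 7.91 ± 1.92, and on chromosome 7, 100550759 to 100550870, plus strand, it was 7.69 ± 1.30. Chromosome 19, 41712901 to 41713148, plus strand, had 7.66 ± 1.13. The widest of the 10, with 1059 bases, lay on chromosome 20 from 62446504 to 62447562 on the minus strand, at 7.31 ± 1.47. By the mean over 3 samples 2 other regions exceeded it, and 9 of the 10 remained among the highest 10. Library 1 gave the lowest value in 10 of the 10 regions. The highest −log10 p of each of these regions lay at or above the ceiling of 15.7 in every library, so their read numbers were not worked out. By the match described above, values at the ceiling itself come from Fisher's exact test, used where a read number is below 5. Such folds may therefore rest on few input reads. Over the 940 regions in all 4 libraries the median of the mean log2 fold was 5.02, and 143 regions reached a mean of at least 6.

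**Figure D1:**
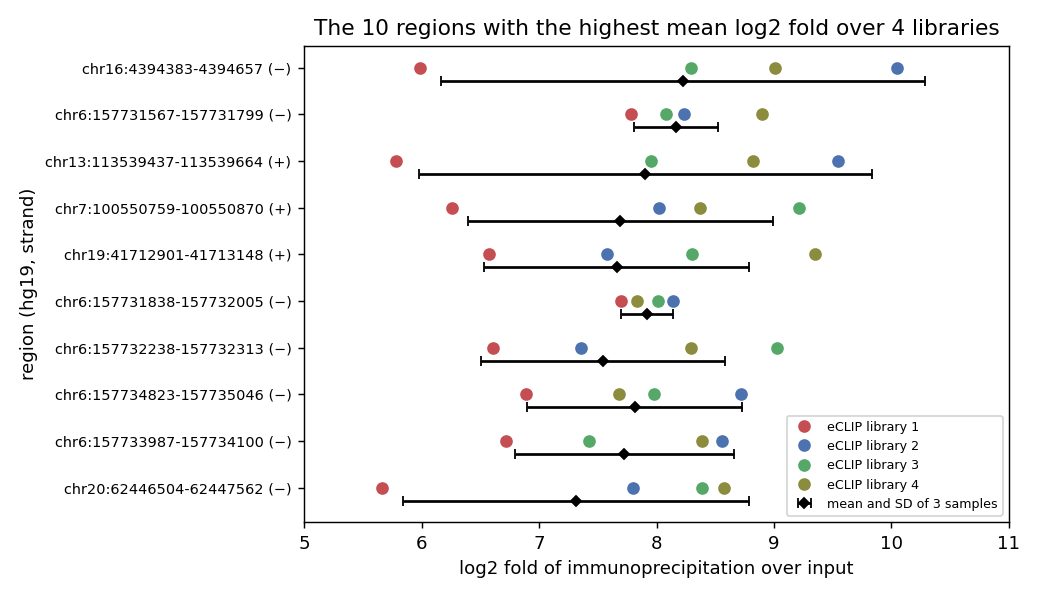
Log2 fold of immunoprecipitation over input (x axis) in the 10 regions with the highest mean over the 4 libraries (y axis, hg19), with a dot per eCLIP library and the mean with SD of 3 samples, libraries 3 and 4 counted as 1, as diamond and bar. Library 1 holds the lowest dot in each region, and single values span 5.66 to 10.04.

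Of these 10 regions, 5 belonged to 1 run on chromosome 6, 157731460 to 157735393, minus strand. The run held 17 reproducible regions in 3934 bases, and all 17 were enriched in all 4 libraries. Their mean log2 fold was 7.26 ± 0.50 (SD over regions). Also among the 10 were 157731838 to 157732005 and 157734823 to 157735046, at 7.92 ± 0.22 and 7.81 ± 0.91 (SD, n = 3), and 157732238 to 157732313 and 157733987 to 157734100, at 7.54 ± 1.04 and 7.73 ± 0.93. The next run, on chromosome 3 from 195505957 to 195509775 on the minus strand, held 13 regions with a mean of 5.48 ± 0.58 (SD over regions). A further 9 regions followed within 195510853 to 195513697 on the same strand, at 5.75 ± 0.52. No filter for repeated or hard-to-map sequence was applied here to any peak, region or run. How the authors placed reads in such sequence is not given in the sources used here. Whether the named regions and runs lie in it was not tested.

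**Figure D2:**
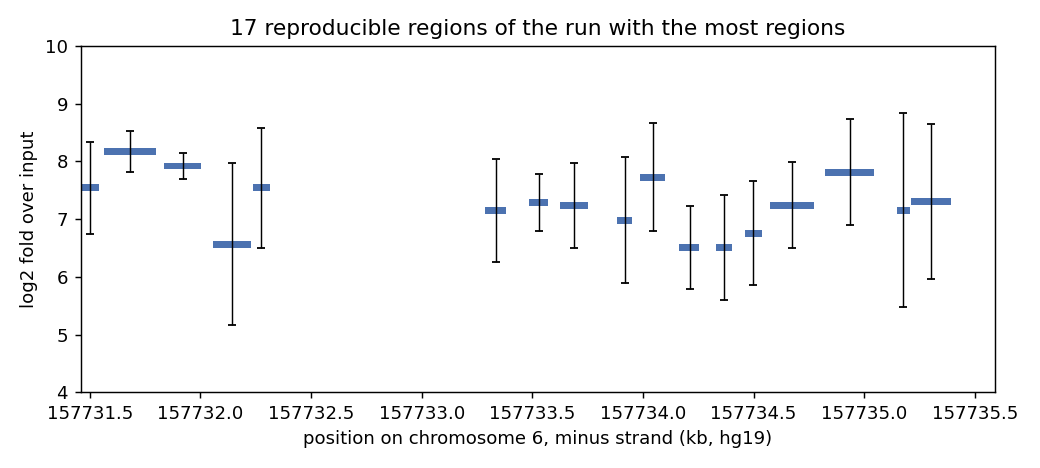
Map of the run on chromosome 6 (x axis, position in kb, hg19, minus strand) with the mean log2 fold over input of each of its 17 regions (y axis). Blue bars span each region and black lines are the SD of 3 samples; means lie between 6.50 and 8.17.

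Runs were examined only after the data were seen. The 1699 regions fell into 1049 runs, and 348 runs held at least 2 regions, with 998 regions (58.7%) in them. At least 4 regions were found in 64 runs. Drawing 1699 of the 7645 regions listed in at least 3 libraries gave 3.19 ± 1.86 such runs (SD of 100 draws), at most 10 (permutation p = 0.0099, the smallest that 100 draws can give). The 7645 were merged from all listed peaks, but the 1699 from enriched peaks only. Other listed peaks can join neighbours into 1 region, so the draws cannot tell clustering from this difference in merging. The number of runs with at least 4 regions rose to 109, 116, 118 and 115 without libraries 1, 2, 3 and 4, where 2 of the other 3 libraries sufficed. Of the 1699 regions, 3 (0.18%) overlapped a reproducible region on the other strand. Among the 7645 regions listed in at least 3 libraries, 0.039% overlapped another of them on the other strand.

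The third comparison asked how closely the libraries agreed. Log2 folds of overlapping peaks correlated with Pearson's r of 0.85 between libraries 3 and 4, 0.80 between 2 and 3, 0.81 between 2 and 4, 0.72 between 1 and 2, 0.75 between 1 and 3 and 0.72 between 1 and 4. These are correlations across peaks, which are not independent replicates. The mean of the 6 pairs was 0.78 ± 0.053 (SD over pairs), with 0.75 ± 0.057 for Spearman's rho. These means take libraries 3 and 4 singly and include their own pair, the highest. With the 2 joined as 1 sample, r was 0.72 between libraries 1 and 2. Against the joined sample it was 0.73 for library 1 and 0.80 for library 2. Over peaks with −log10 p of at least 3 in both libraries the mean r of the 6 pairs fell to 0.59 ± 0.13 (SD over pairs). By sample it was 0.53 between libraries 1 and 2. Against the joined sample it was 0.46 for library 1 and 0.69 for library 2. Of library 3's enriched peaks, the fewest of the 4 lists, 81.8% overlapped an enriched peak of library 4, 78.1% one of library 2 and 63.6% one of library 1. In the other direction, 59.6% of library 4's, 37.2% of library 2's and 42.7% of library 1's enriched peaks overlapped one of library 3. Between libraries 1 and 2 the shares were 59.1% of library 1's and 42.4% of library 2's. Description codes place libraries 1 and 2 in 1 set and 3 and 4 in another. Pairs within a set had r of 0.72 and 0.85, the latter being libraries 3 and 4, counted as 1 sample. The 4 pairs between sets had 0.77 ± 0.041 (SD over pairs). By sample these are only the values of 0.73 for library 1 and 0.80 for library 2.

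**Figure D3:**
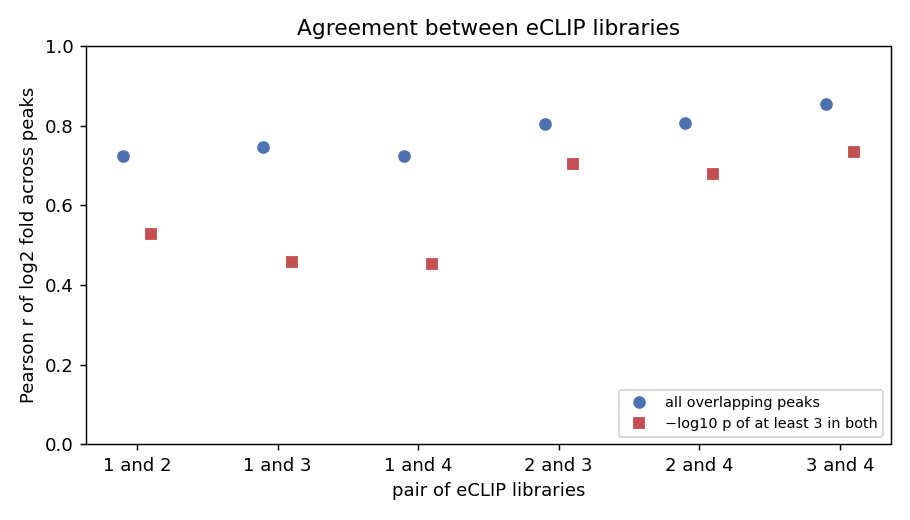
Pearson's r of log2 fold across overlapping peaks (y axis) for each pair of eCLIP libraries (x axis), over all overlapping peaks (circles) and over peaks with −log10 p of at least 3 in both (squares). The 3 pairs with library 1 have the lowest r in both sets, 0.72 to 0.75 for all peaks and 0.45 to 0.53 for the stricter set.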

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

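Of 22 quantities compared over the 4 libraries, with libraries 3 and 4 taken singly, 1 stood apart by Dixon's criterion for 4 values, against about 1.1 that chance would give. Library 2 listed 118375 peaks, and the next highest, library 4, listed 29615, so its distance to the others made up 0.905 of the whole range. The comparison of read numbers was set before its result was seen. Over peaks listed by both, library 2 had 3.16, 3.97 and 2.65 times the immunoprecipitation reads of libraries 1, 3 and 4. With its reads thinned to those of each of them, the number of its peaks that kept at least 3 reads came to between 1.10 and 1.18 times that library's own number. Deeper sequencing of library 2 may therefore account for its long list. No biological explanation was tested, since the libraries belong to 1 group.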

How the results depend on the processing

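No paired analysis was possible because the inputs that share numbers with the eCLIP libraries have no values of their own. The shares in 3′ untranslated regions, the paired CAC motif and the gene lists were not run under any setting, and neither was the replicate block. Settings chosen after seeing the data are the common read minimum, the counting of libraries 3 and 4 as 1 sample, each library left out for the enriched peaks and the named regions, and all those for mitochondrial peaks, runs and chromosome ends.

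The number of reproducible regions was 2935 for at least 2 of 4 libraries, 940 for all 4 and 2788 for at least 2 of 3 samples. With each library left out and at least 2 of the other 3 asked for, it lay between 2188 and 2685; without library 3 it was 2685. In the last 2 settings the libraries and the number asked for changed together, and the cause was not tested. It stayed within 1.5 times the main count for the stricter p (1154), the looser fold (2043), the larger overlap (1696) and a common minimum of 13 reads (1237). Mean enriched peaks stayed within 1.5 times under all alternatives run, from 3254 to 5625. Mean r over pairs, with libraries 3 and 4 taken singly, was 0.59 over peaks with −log10 p of at least 3 in both libraries. It was 0.75 to 0.82 with each library left out. Runs of at least 4 regions numbered 109 to 118 with each library left out and 2 of the other 3 asked for, and the cause was not tested. With each library left out, the named region on chromosome 16 lay between 7.32 and 9.35 in log2 fold, that on chromosome 13 between 7.09 and 8.97, on chromosome 7 between 7.53 and 8.41 and on chromosome 20 between 7.07 and 8.14.

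The mitochondrial difference was 10.5 points, and 1.88 with the looser fold, and the cause was not tested. The excess near chromosome ends, 17.3 points, was 20.7 points with the stricter p, 9.58 within 1 Mb, 13.0 within 2 Mb and 13.5 with close peaks counted once; the odds ratio was 3.04 within 1 Mb, 2.52 within 2 Mb and 2.39 within 5 Mb, and the cause was not tested. Depth limits the log2 fold where input held at most 1 read, which was the case for 35.1% to 63.1% of each library's enriched peaks with recovered reads.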

Other observations

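All comparisons in this part were chosen after seeing the data, and so were the tests on runs of peaks and on library 1; the tests on reads per peak and on single chromosomes were set before their results were seen. Peaks on the mitochondrial chromosome were seldom at least 8-fold enriched. None of 55 listed in library 1, 56 in library 3 and 79 in library 4 reached the thresholds. In library 2, 3 of 119 did, 1 of 115 on the plus strand and 2 of 4 on the minus strand. For libraries 1, 3 and 4, taking 3 counts of each total allows shares of up to 5.45%, 5.36% and 3.8%. The upper ends of the exact two-sided 95% intervals were 6.49%, 6.38% and 4.56%. The shares of nuclear peaks in libraries 1, 3, 4 and 2 were 16.0%, 12.6%, 12.7% and 5.38% (Fisher's exact test within each library, two-sided, p = 1.27e-04, 8.91e-04, 4.91e-05 and 0.22). Over samples the nuclear share was higher by 10.5 ± 6.82 points (SD, n = 3), which fell to 1.88 points with the looser threshold of log2 of at least 1.

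By chromosome, enriched peaks were more frequent in all 4 libraries on chromosome 13 (log2 odds ratio 1.05 ± 0.16, SD, n = 3), 16 (0.66 ± 0.21) and 19 (0.34 ± 0.085), and less frequent on chromosomes 3 (-0.36 ± 0.039), 15 (-0.57 ± 0.31) and X (-0.51 ± 0.25), each with Benjamini-Hochberg adjusted p from Fisher's exact test below 0.05 in all 4 libraries. With peaks at most 5 kb apart counted once, chromosome 19 was higher in 4 libraries and passed in 3 (0.53 ± 0.057), chromosome 3 was lower in 4 and passed in 2 (-0.47 ± 0.082), and chromosomes 13 (0.32 ± 0.25), 15 (-0.25 ± 0.14), 16 (0.29 ± 0.090) and X (-0.058 ± 0.14) passed in 0.

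Enriched peaks lay near chromosome ends more often than other listed peaks, 38.1% ± 5.20 against 20.8% ± 4.84 within 5 Mb (SD, n = 3), a difference of 17.3 ± 1.99 points present in 4 of 4 libraries (exact sign-flip permutation p = 0.25, the smallest possible). A few chromosomes do not account for it, since within chromosomes the lowest of the 4 libraries' odds ratios was 2.04. Nor do a few long runs, since with close peaks counted once the lowest was 2.06. The excess was present in all 4 libraries on 20 of 23 chromosomes. It was present in 3 libraries on chromosome 14 and in only 1 each on chromosomes 15 and X. Reads per peak stay open as part of it: among peaks with recovered reads the odds ratios in libraries 1 to 4 were 1.72, 1.88, 2.55 and 2.15, and within bins of immunoprecipitation reads 1.23 (95% interval 1.09 to 1.39), 1.28, 1.80 and 1.67. Runs of at least 4 regions lay near an end in 35 of 64 cases against 210 of 701 single regions (Fisher's exact test, two-sided, p = 1.18e-04). No biological explanation was tested.

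Library 1 had the lower correlations, with r of 0.72 against library 2 and 0.73 against the sample of libraries 3 and 4, where library 2 and that sample had 0.80. With 3 samples a single pair lacks library 1, so no spread can be given. Few immunoprecipitation reads per peak would let the gap close in deep peaks. With at least 20 of them, or a −log10 p at or above the ceiling, in both libraries the difference was -0.16 (bootstrap SE 0.023, over stretches of the genome and not over samples). No minimum was set for input reads, and peaks with log2 of 0 or less dropped out, having no recovered reads. Few input reads are therefore not excluded. A batch by description code is not the whole cause, since it would keep libraries 1 and 2 together. Their r was lower than that of library 2 with libraries 3 and 4, with a difference of -0.081 (bootstrap SE 0.0097). These are the same r values that set library 1 apart, so they are no separate test. Library 1's deeper input relative to its immunoprecipitation, 3.18 times, and its handling stay open.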
